A study of Mus musculus with 25 samples.

How the data were processed

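Genomic DNA from mouse embryonic stem cells was collected 48 h after transfection, and translocation junctions were mapped by linear amplification-mediated high-throughput genome-wide translocation sequencing (LAM-HTGTS), per the labels' protocols. In this assay a Cas9 cut serves as the bait, DNA joined to the bait end is amplified from a primer next to the cut, and each read gives the position and orientation of the joined (prey) DNA. The bait lay 30 kb from a 4-kb reporter cassette in the ROSA26 locus, DNA was sonicated, XbaI was used for blocking, and libraries were sequenced on a MiSeq, per the labels. Bowtie2 and mm9 are named in the submitters' processing notes. Filters, removal of duplicates and any scaling of junction numbers by the authors were not given in the sources used here.

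The authors deposited 1 table per group, with 1 row per junction and the other columns holding strand, alignment start and end, read name and read sequence. The values are positions and sequences, not counts. The tables analysed here listed 11867 junctions, all on 1 reference named chromosome 1 with positions from 1 to 3928. Those positions span the cassette, so the reference was read as a cassette sequence and all coordinates here are 1-based cassette coordinates, not coordinates of a genome build. Junctions next to the bait or elsewhere in the genome were not analysed here. The planned share of cassette junctions among all junctions, the bait-proximal share, the share on other chromosomes, the windows of other widths and the recurrent prey regions with their gene lists therefore could not be computed. Junction numbers were not used as breakage frequencies, because the number of all junctions per library was not used here.

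The cassette sequence was rebuilt from the reads by voting over 5 passes of ungapped placement, and features were located in it by exact match. Reads held 1 base more than the deposited coordinates between the last Ter element and EGFP, in 152 of 160 reads spanning that stretch, and this base was put into the sequence used for junction structure. The array window ran from 3025 to 3276, the cassette body from 1 to 3616 and the polyA region from 3617, the last XbaI site, to 3928. The array holds a pair of identical repeats of 117 bp. A read that ended within the array could be placed in either repeat, so positions within the array were described only for reads that reached at least 20 bp of unique sequence beyond it. Prey orientation is called leftward where the joined DNA ran from the junction toward position 1 (minus strand) and rightward where it ran toward position 3928 (plus strand).

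Junction structure was called from each read. The bait part was extended from an exact 10-bp seed and the prey part from an exact 12-bp seed, and bases shared by both parts were microhomology, bases in neither an insertion, and joins with neither were blunt. Structure was called for 11810 junctions (99.5%). Microhomology was counted from 2 bp, the planned minimum. The share expected by chance came from 20 random pairings of the same bait ends and prey positions within a group. Such pairings hold no inserted bases, whereas the observed shares count joins with an insertion in their denominator. The excess of observed microhomology over random pairing is therefore understated, and the shortfall of blunt joins overstated. Tested on simulated data for array joins, the caller gave the exact overlap in 99.9% of 2000 random joins without read errors and in 94.8% of 2000 with 0.3% errors per base.

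The labels list 25 samples in 10 groups. The tables pool the samples of a group and carry no replicate number, but read names carry a sequencing run. There were 4 runs, here called A to D, and in each of the 10 groups the number of runs equalled the number of samples. Each run of a group was treated as 1 library, although nothing in the tables ties a run to a labelled replicate. Run C held all 10 groups, run D the 8 Tus groups, run B 4 groups and run A 3 groups. Libraries held 148 to 933 junctions. Nothing in the labels says whether replicates were separate cultures, so p-values over runs measure the spread between these libraries, which may be technical.

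Shares are given as the mean ± SD over runs, or pooled over runs with Wilson 95% intervals. Amplified reads are not independent molecules, so these intervals and the tests on pooled junctions cover counting error only. Runs of a group differed beyond counting error (unadjusted permutation p below 0.05, 2000 resamples) in 7 of 10 groups for the body share. For microhomology this held in 5 of 9 groups, for the rightward share in 2 of 9 and for blunt joins in 1 of 9. Where runs differ, p-values on pooled junctions are too small as a measure of the difference between conditions. No read name was repeated and no read sequence was repeated within a group. Pairs of groups were compared by a two-sided Fisher's exact test on pooled junctions and by an exact permutation test over runs. Both tests were fixed before the data were examined. Fisher's p was adjusted by Benjamini-Hochberg over the comparisons of 1 measure (13 for the body share, 11 for the others, in which the empty vector had too few joins). The plan put the permutation test first if replicates could be told apart. For 1 pair of groups it cannot give p below 0.10 here, so no pairwise difference passed by it. Pairwise calls below rest on Fisher's exact test. The body share was defined after the data were examined, in place of the planned share of cassette junctions among all junctions. Genotype was combined over the 4 siRNAs as a Mantel-Haenszel common odds ratio with an exact conditional p, and tested by exact permutation of runs between genotypes within each siRNA (20000 splits). Because runs A and B were not spread evenly over genotypes, the genotypes were also compared within runs C and D, as 8 pairs matched for run and siRNA with an exact sign-flip test (256 sign patterns), chosen after seeing the data. The sign-flip test takes the 8 pairs as independent, although each of these runs gave 4 of them. A genotype difference particular to a run is therefore not covered by its p-values. The genotype by siRNA interaction was tested by a likelihood-ratio test in a binomial model of pooled junctions and by 20000 permutations of residuals of log odds within runs, and, chosen after seeing the data, of percentage points. Positions were compared by a rank permutation test of single junctions with 100000 resamples, or 10000 within runs. On simulated libraries of the observed sizes, permutation within siRNAs gave p below 0.05 in 5.67% of 300 rounds with no genotype effect and in 100% of 300 rounds with rightward shares of 15% and 5%. These libraries were drawn with no differences between runs or siRNAs, so the rates do not cover the spread between runs. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. Alternatives covered unique junctions, other microhomology minimums, windows, uniquely placed reads, shared runs and leaving out each run or siRNA.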

Results

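Translocation junctions were mapped from a Cas9-cut bait to a reporter cassette 30 kb away in the ROSA26 locus of mouse embryonic stem cells. The cassette carries 6 Ter elements, the binding sites of the bacterial protein Tus, which blocks replication forks when bound, next to a site for the homing endonuclease I-SceI. Cells received Tus, I-SceI or a control that the labels call EV (read here as empty vector), together with a small interfering RNA (siRNA) against BLM (a RecQ helicase), BRCA1 (a mediator of homologous recombination), FANCM (a DNA translocase that acts at stalled forks) or luciferase as the control. The 2 genotypes are given in the labels as BRCA1del/exon11 and BRCA1flox/exon11, and are called BRCA1del and BRCA1flox here. The series title concerns tandem duplications that form through microhomology where forks stall at Tus/Ter, and the role of BRCA1 in limiting them.

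The 25 samples fell into 10 groups. Tus was tested with all 4 siRNAs in both genotypes, with 3 samples per group in BRCA1del, 3 for siFANCM in BRCA1flox and 2 for each other siRNA in BRCA1flox. EV and I-SceI were tested in BRCA1del with siFANCM, with 2 samples each. The tables held 11867 junctions over 25 libraries, with 148 to 933 junctions per library. Group totals ranged from 468 junctions for EV to 1702 for I-SceI. Each sequencing run of a group is taken as 1 library, errors over runs are SD, and all tests were two-sided.

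The features of the cassette were placed in its own coordinates. The 6 Ter elements, each with the sequence AATAAGTATGTTGTAACTAAAGT, lay at 3049 to 3071, 3077 to 3099, 3105 to 3127, 3166 to 3188, 3194 to 3216 and 3222 to 3244, all in the same orientation. The I-SceI site, TAGGGATAACAGGGTAAT, followed at 3259 to 3276. The array and the I-SceI site interrupted the EGFP coding sequence, which began at 2637 and ended at 3604. A polyA region began at the XbaI site at 3617, with an SV40 polyA segment at 3767 to 3795 and a bovine growth hormone polyA segment at 3856 to 3900.

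The first comparison asked which joins depended on Tus or I-SceI, in BRCA1del cells with siFANCM. With EV, 5 of 468 junctions lay in the cassette body and 463 lay in the polyA region, so that the body held 1.07% ± 0.01 of junctions (n = 2 runs). The body share was 63.3% ± 3.3 with Tus (n = 3 runs) and 67.0% ± 4.5 with I-SceI (n = 2 runs). Both differed from EV on pooled junctions (adjusted p = 2.4e-144 for Tus and 5.7e-172 for I-SceI, Fisher's exact test), and the effector library had the higher share in both runs shared with EV. The split into cassette body and polyA region was chosen after the data were examined. Over runs the exact permutation p was 0.10 for Tus and 0.333 for I-SceI, the smallest these designs allow. Only 1 EV junction lay in the array window, against 687 with Tus and 815 with I-SceI. Over all groups 51.3% of placed polyA-region reads ran on into sequence that was neither cassette nor adapter, against 2.95% of body reads, and every body share has these junctions in its denominator.

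**Figure D1:**
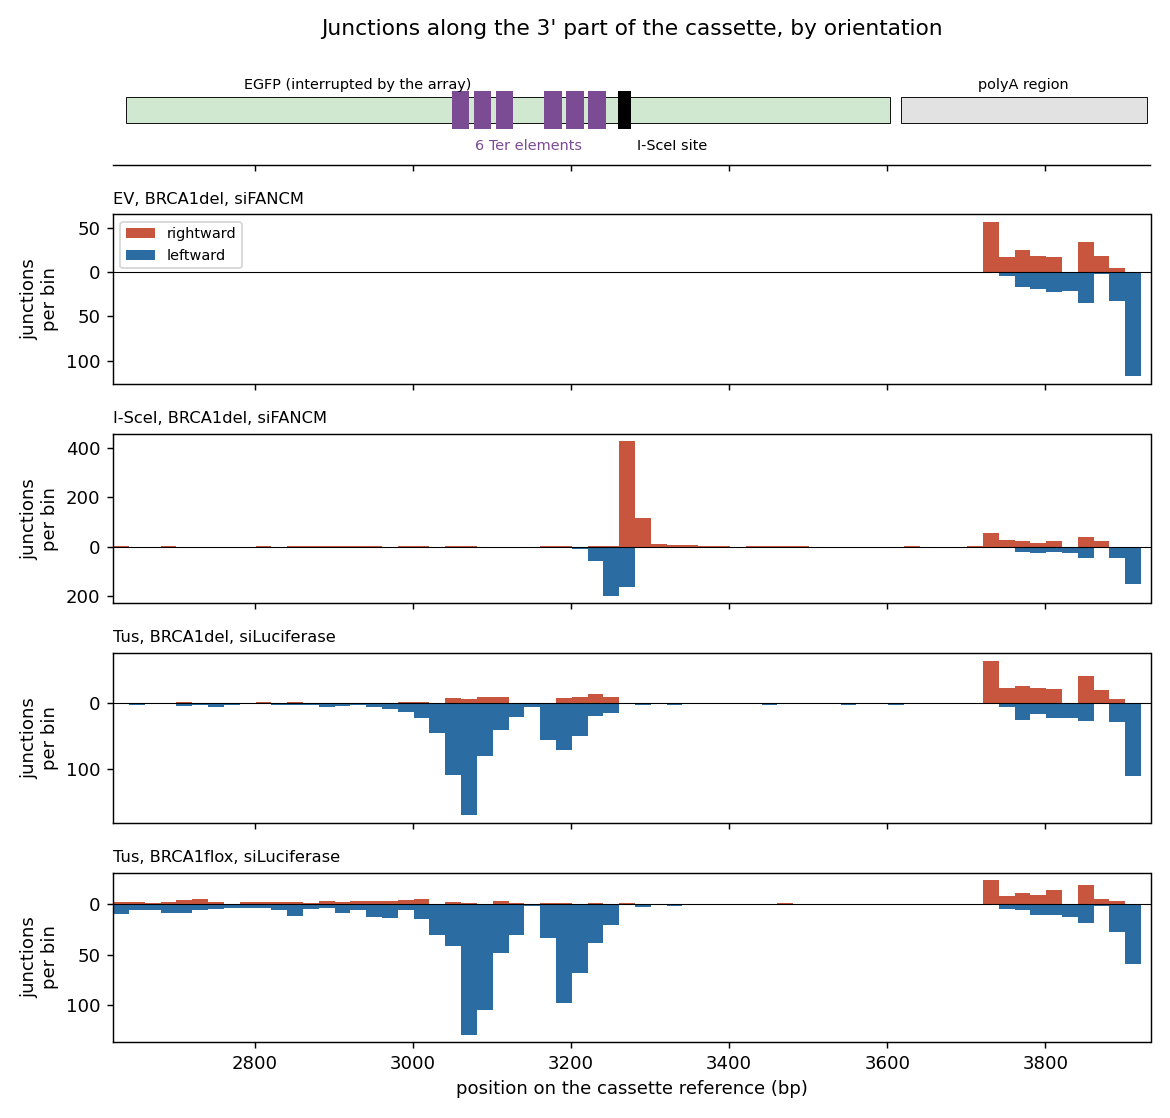
Junctions per 20-bp bin (vertical axis) against position on the cassette reference in bp (horizontal axis) for 4 groups pooled over runs, with rightward joins above and leftward joins below the line, and the cassette features drawn to scale on top. The vertical scales differ between groups, and 3, 26, 48 and 78 junctions before position 2621 are left out for EV, I-SceI, BRCA1del siLuciferase and BRCA1flox siLuciferase. EV junctions lie in the polyA region, I-SceI joins flank the I-SceI site on both sides, and Tus joins are mostly leftward and lie over the Ter elements. Array joins are drawn at their listed positions, including reads that could lie in either repeat. In BRCA1flox siLuciferase 386 of 634 leftward array joins were uniquely placed, 29 of them from the fifth Ter element on.

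I-SceI and Tus joins differed in orientation and position. With I-SceI, 455 array joins were leftward and 360 rightward, a rightward share of 44.1% ± 2.1 (n = 2 runs), and the rightward median position among uniquely placed reads was 3268 (interquartile range 3266 to 3272), within the I-SceI site. With Tus in the same cells, 9.70% ± 7.82 were rightward (n = 3 runs), and the pooled difference of -31.9 percentage points passed the test (12.2% against 44.2%, adjusted p = 6.5e-43, Fisher's exact test; exact permutation p over runs = 0.10, the smallest possible). Among the 461 of 603 leftward Tus joins that were uniquely placed, the median position was 3070 (interquartile range 3056 to 3099), at the first Ter element, and 84.6% lay at or before the end of the third Ter element. Among the 62 of 84 rightward joins that were placed, the median was 3223.5, and 50 lay from the fifth Ter element on. In the other 3 BRCA1del Tus groups the leftward medians were 3067 to 3071 and the rightward medians 3216 to 3227. Placement required a read to reach the flank it ran toward, which favours leftward joins near the left end and rightward joins near the right end, so part of this contrast is built in. Of all leftward Tus joins in the same cells, placed or not, at least 64.7% lay up to the third Ter element, and of all rightward joins at least 59.5% lay from the fifth on. When each position and strand was counted once per library, which removes repeated use of the I-SceI cut, the orientation difference was -4.36 points and did not pass (adjusted p = 0.319, Fisher's exact test). Among uniquely placed reads, which kept 71 of 455 leftward and 356 of 360 rightward I-SceI joins, it was -71.5 points, and within the span of the Ter elements, which leaves out the I-SceI site, it turned to 8.90 points (adjusted p = 0.0062, Fisher's exact test). With each position and strand counted once, the body share with Tus exceeded that with I-SceI by 10.6 points, the opposite of the difference of -5.01 points among the listed junctions, which did not pass without run A or without run C (-5.14 and -3.24 points).

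The structure of the joins also differed between the effectors. Array joins with I-SceI were blunt in 37.9% ± 6.9 and carried microhomology of at least 2 bp in 17.5% ± 0.9 (n = 2 runs), against 14.8% microhomology expected from random pairing of the same ends. Tus joins in the same genotype and siRNA were blunt in 21.8% ± 5.6 and carried microhomology in 38.3% ± 9.6 (n = 3 runs), against 17.3% expected by random pairing. Random pairing gave 55.5% blunt joins for I-SceI and 53.6% for Tus, above the observed blunt share of each. Only the observed shares count insertions in their denominator, 20.4% of the pooled I-SceI joins and 13.4% of the pooled Tus joins. On pooled junctions both differences passed (adjusted p = 4.1e-13 for microhomology and 5.9e-08 for blunt joins, Fisher's exact test), and both had the same direction in runs A and C. With each position and strand counted once, neither passed (differences of 8.75 and -1.56 points). Within the span of the Ter elements, which leaves out the I-SceI site, the differences were 1.82 and -1.32 points and did not pass (adjusted p = 0.756 and 0.724, Fisher's exact test).

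The genotype comparison asked how the joins at the Tus-bound array differed between BRCA1del and BRCA1flox cells. Rightward array joins made up 10.7% ± 3.0 in BRCA1del with siLuciferase (n = 3 runs) and 1.56% ± 0.39 in BRCA1flox (n = 2 runs), and pooled counts were 78 of 757 and 11 of 645. The rightward share in BRCA1del and BRCA1flox was 16.6% ± 1.6 and 8.36% ± 0.94 with siBLM, 16.3% ± 2.8 and 9.71% ± 1.98 with siBRCA1, and 9.70% ± 7.82 and 8.86% ± 3.78 with siFANCM. Over the 4 siRNAs the common odds ratio was 2.14 (95% interval 1.75 to 2.62), and the mean share was 13.3% in BRCA1del and 7.12% in BRCA1flox (exact permutation of runs within siRNAs, p = 0.00305, adjusted p = 0.00915 over 6 measures). Within runs C and D the share was higher in BRCA1del in 7 of 8 pairs, by 5.69 points on average (exact sign-flip p = 0.0234, adjusted p = 0.0352). Pairwise, the genotypes differed on pooled junctions with siLuciferase (adjusted p = 1.9e-11), siBLM (0.00015) and siBRCA1 (0.0013) but not with siFANCM (0.0685, Fisher's exact test), where the call and direction depended on the runs. That difference was 3.21 points pooled, -0.301 within shared runs and -3.21 without run A, and it passed at 5.87 points without run B, 4.28 without run D and 3.76 within the span of the Ter elements. Without run C the siBRCA1 difference was 3.21 points and did not pass. In the whole cassette body, which adds rightward joins left of the array, the common odds ratio was 1.19, and the pairwise difference passed with none of siBLM, siBRCA1 and siLuciferase.

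**Figure D2:**
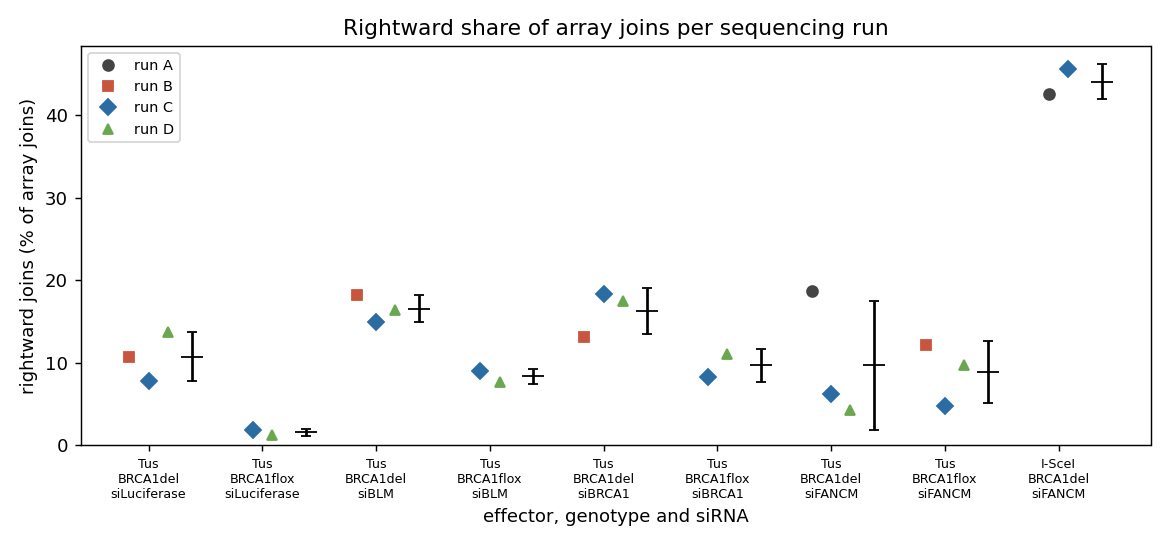
Rightward joins as a percentage of array joins (vertical axis) for each sequencing run of the 8 Tus groups and the I-SceI group (horizontal axis), with symbols for runs A to D and the mean ± SD over runs in black beside them. Both runs of BRCA1flox siLuciferase lie below 2%, and the 3 runs of BRCA1del siFANCM spread from 4.23% to 18.7%.

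The odds ratio between the genotypes varied with the siRNA. On the log-odds scale the interaction of genotype and siRNA passed on pooled junctions (adjusted p = 0.00021, likelihood-ratio test) and over runs (adjusted p = 0.0016, permutation of residuals). The odds ratio of BRCA1del over BRCA1flox was 6.62 with siLuciferase, 2.15 with siBLM, 1.90 with siBRCA1 and 1.41 with siFANCM, the last falling to 0.947 within shared runs. In percentage points the pooled differences were 8.6, 8.19, 6.88 and 3.21, so that siLuciferase stood apart on the odds scale, from a share of 1.71% in BRCA1flox, and not in points. The interaction in percentage points over runs had an adjusted p of 0.0432 (permutation of residuals).

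Array joins in BRCA1del were more often blunt than in BRCA1flox. The blunt share was 16.7% ± 2.4 against 8.46% ± 1.92 with siLuciferase, 19.3% ± 5.8 against 7.52% ± 1.67 with siBLM, 20.1% ± 1.4 against 12.7% ± 4.4 with siBRCA1 and 21.8% ± 5.6 against 11% ± 1.4 with siFANCM (n = 3 runs in BRCA1del and in BRCA1flox siFANCM, 2 in the other groups). Random pairing of the same ends gave 51.5% to 53.6% blunt joins in the 8 Tus groups, above the observed pooled share in each. As above, random pairs hold no insertions. All 4 pairwise differences between the genotypes passed on pooled junctions (adjusted p from 4.4e-09 to 0.011, Fisher's exact test) and in shared runs. The common odds ratio was 2.20 (95% interval 1.86 to 2.59; exact permutation p = 5e-05, the smallest these splits can give, adjusted p = 0.0003). The share was higher in BRCA1del in 8 of 8 run-matched pairs, by 8.75 points on average (exact sign-flip p = 0.0078, the smallest possible, adjusted p = 0.0234). With siLuciferase and each position and strand counted once, the difference was 3.82 points and did not pass. With siBRCA1 it was 10.6 points without run C, and 5.08 points without run D, which did not pass.

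Microhomology of 2 bp or more was less frequent in BRCA1del. The share was 41.3% ± 3.3 against 56.3% ± 17.1 with siLuciferase, 42.4% ± 9.8 against 52.0% ± 10.1 with siBLM, 38.8% ± 6.0 against 48.8% ± 8.4 with siBRCA1 and 38.3% ± 9.6 against 47.5% ± 3.4 with siFANCM, with the same numbers of runs. Random pairing of the same ends gave 17.3% to 20.1% in the 8 Tus groups, below the observed pooled share in each. As above, only the observed shares count joins with an insertion in their denominator. The common odds ratio was 0.664 (95% interval 0.592 to 0.745; exact permutation p = 0.00635, adjusted p = 0.0127), and the share was lower in BRCA1del in 8 of 8 run-matched pairs, with a mean difference of -10.1 points (exact sign-flip p = 0.0078, adjusted p = 0.0234). Each of the 4 pairwise differences passed on pooled junctions (adjusted p from 5.2e-05 to 0.0067, Fisher's exact test), and 3 of 4 passed within shared runs, with siBRCA1 at -7.30 points not passing. They rested on the 2-bp minimum: with at least 1 bp or at least 4 bp none passed, and with at least 1 bp the siLuciferase difference turned from -8.01 to 0.738 points, although the common odds ratios of 0.873 and 0.717 did. Without run D none of siBLM (-7.54 points), siBRCA1 (-7.60) and siLuciferase (-0.979) passed, without run C these differences were -16.6, -17.4 and -26.8 points, and without run B siBRCA1 (-7.41) did not pass. Within the span of the Ter elements the siLuciferase difference was -6.42 points and did not pass. Joins with an insertion made up 14.6% on average in BRCA1del and 19.9% in BRCA1flox, a difference that did not pass by exact permutation of runs (p = 0.0517) but passed over the 8 run-matched pairs, of which 6 were lower in BRCA1del (exact sign-flip p = 0.0312, adjusted p = 0.0375).

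**Figure D3:**
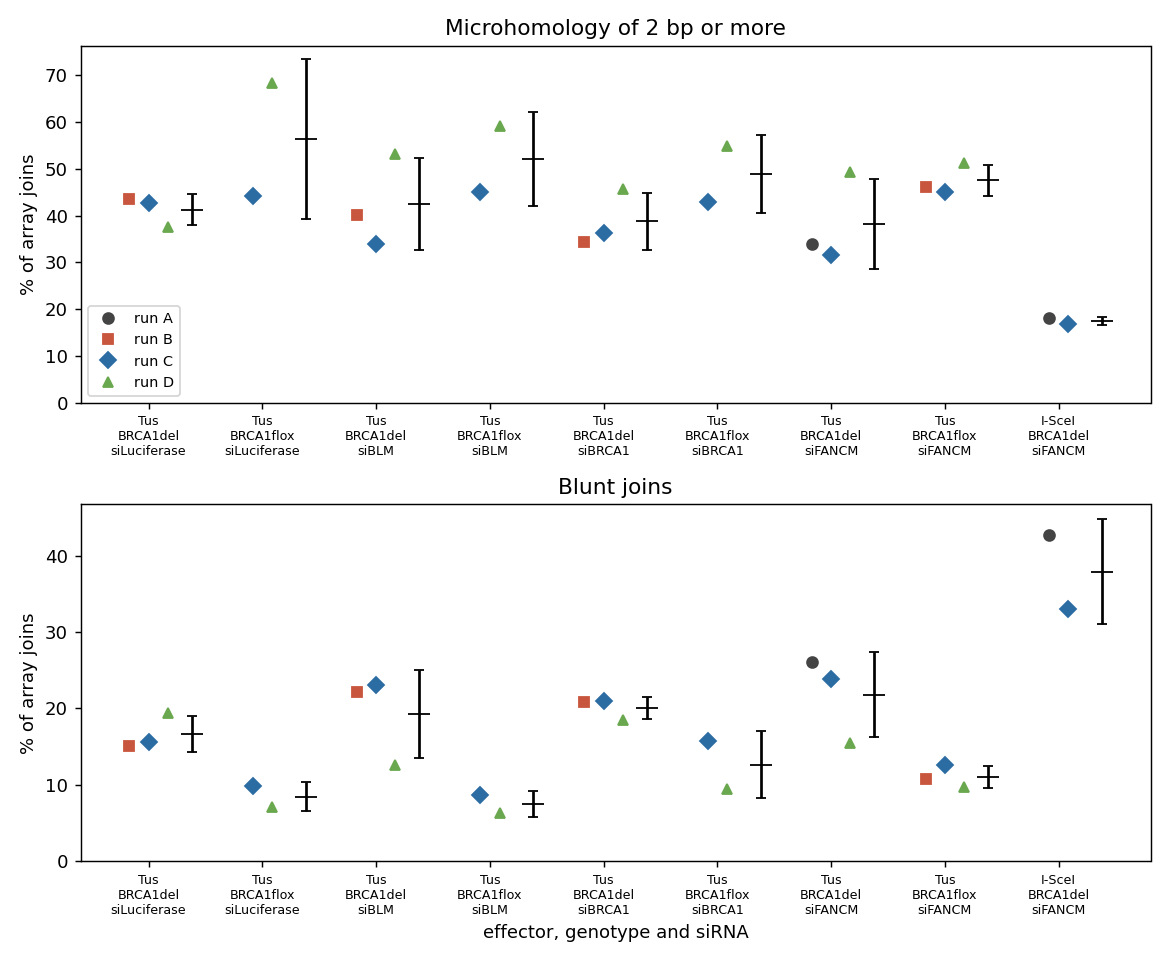
Microhomology of 2 bp or more (top) and blunt joins (bottom) as a percentage of array joins (vertical axes) for each sequencing run of the 8 Tus groups and the I-SceI group (horizontal axis), with the mean ± SD over runs in black. Within runs C and D each BRCA1del group has a lower microhomology share and a higher blunt share than the BRCA1flox group with the same siRNA.

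Uniquely placed leftward joins lay nearer to the left end of the array in BRCA1del with siLuciferase and siBLM. The median was 3071 in BRCA1del and 3086.5 in BRCA1flox with siLuciferase, and 3067 and 3075 with siBLM. Both differences passed (adjusted p = 4.0e-05 and 6.0e-05, rank permutation test) and passed within shared runs. The unadjusted p with siLuciferase, and both within shared runs, were the smallest these resamples can give. This test permutes single junctions and so covers counting error only, and no test over runs was made for positions. Medians with siBRCA1 were 3068 and 3070 and their difference did not pass (adjusted p = 0.532, rank permutation test). With siFANCM they were 3070 and 3072 (adjusted p = 0.0289, rank permutation test), a difference that did not pass within shared runs (adjusted p = 0.125). Placed reads made up 76.5% of leftward array joins in BRCA1del and 64.6% in BRCA1flox, and where the remaining joins lay is not known. Leftward joins beyond the array, in the 3024 bp to its left, made up 15.9% of leftward joins in BRCA1del and 20.5% in BRCA1flox on average (common odds ratio 0.671, 95% interval 0.584 to 0.772; exact permutation p = 0.0104, adjusted p = 0.0149). Within runs C and D that share was lower in BRCA1del in 7 of 8 pairs (exact sign-flip p = 0.117).

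The cassette body held a smaller share of junctions in BRCA1del than in BRCA1flox, with the polyA region holding the rest. The body share averaged 64.1% and 71.9% (common odds ratio 0.744, 95% interval 0.682 to 0.811; exact permutation p = 0.0124, adjusted p = 0.0149), and was lower in 7 of 8 run-matched pairs (exact sign-flip p = 0.0156). With siLuciferase it was 66.5% ± 6.1 and 82.2% ± 6.9, a pooled difference of -13.9 points (adjusted p = 1.2e-14, Fisher's exact test). The differences with siBLM (-2.75 points, adjusted p = 0.191) and siFANCM (-3.66 points, adjusted p = 0.0672) did not pass by Fisher's exact test, and both depended on the runs. With siBLM the difference passed within shared runs (-8.29 points) and without run B (-8.55), and turned to 0.372 points without run D. With siFANCM it was -0.481 points within shared runs and -0.804 without run A, and it passed without run C (-6.83). With siBRCA1 the pooled difference of -4.82 points passed (adjusted p = 0.0345, Fisher's exact test) and was -8.23 points without run C. It did not pass without run D (-3.52), with each position and strand counted once (-5.41) or with the same position, strand, far end and bait end counted once (-3.78). The interaction with siRNA passed on pooled junctions (adjusted p = 1.5e-05) but not over runs (adjusted p = 0.0805, permutation of residuals).

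The siRNA comparisons asked how depleting BLM, BRCA1 or FANCM altered the joins relative to siLuciferase. In BRCA1flox the rightward share of array joins rose from 1.71% (95% interval 0.955 to 3.03) to 8.57% with siBLM, 9.11% with siBRCA1 and 9.02% with siFANCM, on pooled junctions (adjusted p = 3.3e-07, 8.4e-08 and 6.3e-09, Fisher's exact test). All 3 siRNAs gave the higher share in both shared runs. They were set against the same siLuciferase libraries, with 9 of 490 and 2 of 155 rightward joins, so these comparisons are not independent. Exact permutation p over runs was 0.333 for siBLM and for siBRCA1, the smallest possible, and 0.2 for siFANCM. In BRCA1del the rightward share rose from 10.3% to 16.8% with siBLM and 16.0% with siBRCA1 (adjusted p = 0.00051 and 0.0022, Fisher's exact test), each higher in 3 of 3 shared runs. With siFANCM in BRCA1del it was 12.2% (adjusted p = 0.278, Fisher's exact test), and within runs C and D it was lower than with siLuciferase in both. That difference of 1.92 points passed in opposite directions without run A (-4.49 points, adjusted p = 0.0178) and without run D (3.77 points, adjusted p = 0.0457, Fisher's exact test). Over both genotypes, the exact permutation of runs gave p = 0.0167 for siBLM, the smallest its 120 splits can give, 0.0333 for siBRCA1 and 0.32 for siFANCM (adjusted p = 0.05, 0.05 and 0.32). None of these was below the threshold of 0.05 on adjusted p. The rightward share was higher in 5 of 5 shared runs with siBLM and with siBRCA1, and in 2 of 4 with siFANCM. For siBLM and for siBRCA1 the exact sign-flip p over these pairs was 0.0625, the smallest that 5 pairs can give. Among reads placed uniquely, the siBLM differences were 3.87 and 2.28 points and did not pass, and without run C the siBRCA1 difference in BRCA1del was 2.62 points and did not pass. In the whole cassette body the siBRCA1 difference in BRCA1flox was 3.73 points and did not pass. Without run B the siFANCM difference in BRCA1flox was 4.65 points and passed.

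The siRNAs were also compared for junction structure. Relative to siLuciferase the pooled blunt share was higher in BRCA1del with siBLM, siBRCA1 and siFANCM (21.5%, 20.5% and 24.1% against 16.2%) and in BRCA1flox with siBRCA1 (14.0% against 9.16%), with adjusted p from 0.00046 to 0.0453 by Fisher's exact test. Within shared runs 2 of these 4 passed, siBLM in BRCA1del and siBRCA1 in BRCA1flox, and neither passed without run C (4.00 and 2.43 points). Of 6 microhomology comparisons 1 passed, siFANCM in BRCA1del (34.6% against 42.0%, adjusted p = 0.0075, Fisher's exact test), and it did not pass within shared runs (adjusted p = 0.238). The set depended on the runs: without run C the BRCA1flox differences with siFANCM and siBRCA1 passed at -20.8 and -13.6 points, against -3.35 and -3.67 pooled, and without run D siBRCA1 in BRCA1del passed at -7.89 points. Without run A, run B or run C siFANCM in BRCA1del did not pass (-6.71, -6.19 and -5.00 points). Over both genotypes no siRNA passed for blunt joins or microhomology by exact permutation of runs (lowest adjusted p = 0.12).

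The body share fell with each siRNA in BRCA1flox, from 79.4% to 70.2% with siBLM, 64.2% with siBRCA1 and 65.8% with siFANCM (adjusted p = 3.9e-06, 3.5e-14 and 7.9e-14, Fisher's exact test). In BRCA1del it fell from 65.5% to 59.3% with siBRCA1 (adjusted p = 0.0015, Fisher's exact test), and with each position and strand counted once the difference was -1.59 points and did not pass. It was 67.4% with siBLM and 62.1% with siFANCM (adjusted p = 0.314 and 0.0799, Fisher's exact test). The siBLM difference of 1.87 points turned to -1.57 without run B. The siFANCM difference of -3.40 points turned to 2.37 within shared runs, and passed at -8.92 without run C. Over both genotypes the exact permutation of runs gave adjusted p = 0.075 for siBRCA1 and siFANCM and 0.3 for siBLM.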

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

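The likelihood-ratio test of the interaction and its test by permutation were planned before the data were examined, except in percentage points. The body share to which they were applied was defined afterwards. The tests of the repeated counting of amplified junctions and of the mix of orientations were set out before their results were seen. The other tests in this part were chosen after the result was seen.

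The interaction of genotype and siRNA differed from none on pooled junctions (likelihood-ratio test) for 3 shares. For the rightward share of array joins the adjusted p was 0.00021 on pooled junctions and 0.0016 by permutation of residuals over runs. For the body share these were 1.46e-05 and, by permutation, 0.0805, and for the blunt share 0.0453 and, by permutation, 0.438. In percentage points the rightward interaction had adjusted p = 0.0432 by permutation. For the rightward share the genotype odds ratio was 6.62 with siLuciferase and 1.41 to 2.15 with the other siRNAs, with BRCA1flox siLuciferase at 1.71%.

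Rightward array joins were more frequent in BRCA1del than in BRCA1flox over the 4 siRNAs. Sequencing runs held by only one genotype are argued against, since within shared runs the common odds ratio was 2.19 (95% interval 1.71 to 2.81). Misplacement of reads within the repeated array is argued against by the direct orientation of the repeats, between which a move keeps the strand, and by uniquely placed reads, with 2.56 (1.92 to 3.41), although these kept 61.4% of rightward joins in BRCA1del and 44.8% in BRCA1flox. Repeated counting of amplified junctions is argued against by unique positions, with 2.02 (1.63 to 2.52). These values are for the array window. In the whole cassette body, which adds rightward joins left of the array, the common odds ratio was 1.19. Genotype, the explanation that the design names, showed a difference over the 8 run-matched pairs (exact sign-flip p = 0.0234) and stays a hypothesis found and tested on the same data, left open for siFANCM, where the pairs in runs C and D went opposite ways.

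Blunt array joins were more frequent in BRCA1del. Within shared runs the common odds ratio was 2.05 (95% interval 1.68 to 2.50), which argues against sequencing runs held by only one genotype. Among leftward joins alone it was 2.19 (1.84 to 2.61), which argues against a different mix of orientations. Genotype showed a difference over the 8 run-matched pairs (exact sign-flip p = 0.0078, the smallest possible), and stays a hypothesis for the same reason.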

How the results depend on the processing

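Of the alternatives here, counting junctions with the same position, strand, far end and bait end once, shared runs as strata, the Ter elements alone, the whole body, uniquely placed reads and the interaction in percentage points were chosen after the data were examined. All 75 alternative values of the 6 combined genotype odds ratios kept their direction and passed the exact test on pooled junctions, in ranges of 1.19 to 2.57 (rightward), 2.0 to 2.79 (blunt), 0.503 to 0.873 (microhomology), 0.584 to 0.75 (insertion), 0.625 to 0.733 (left flank) and 0.665 to 0.848 (body). Over all 52 tested differences, 364 of 449 alternative values kept direction and side of the threshold, 54 lost it, 12 gained it and 19 turned direction. Differences below are in percentage points, siRNAs are against siLuciferase, and genotype means BRCA1del minus BRCA1flox. Except where a construction is named, the cause was not tested.

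Counting each position and strand once merges repeated use of the I-SceI cut, and gave Tus minus I-SceI as 10.6 (body, turned), -4.36 (rightward), 8.75 (microhomology) and -1.56 (blunt), the last 3 no longer passing. It also ended the body calls for siBRCA1 in BRCA1del (-1.59) and genotype with siBRCA1 (-5.41), the microhomology call for siFANCM in BRCA1del (-6.50), and the blunt calls for siBRCA1 in BRCA1flox (1.82) and genotype with siLuciferase (3.82), while microhomology for siFANCM in BRCA1flox passed (-11.2). Adding the far and bait ends ended 1 call, the body share for genotype with siBRCA1 (-3.78). Within shared runs, siFANCM in BRCA1del turned for the body (2.37) and rightward (-3.67) shares, genotype with siFANCM turned for the rightward share (-0.301), genotype with siBLM passed for the body (-8.29), and calls were lost for microhomology (-5.02 for siFANCM in BRCA1del, -7.30 for genotype with siBRCA1) and blunt joins (4.40 for siBRCA1 and 5.04 for siFANCM in BRCA1del). The Ter elements alone leave out the I-SceI site, which turned Tus minus I-SceI for the rightward share (8.90) and ended its microhomology (1.82) and blunt (-1.32) calls. That window also gave 3.76 for genotype with siFANCM (rightward, now passing), -6.42 for genotype with siLuciferase and 1.18, turned, for siBLM in BRCA1flox (microhomology), and 3.23 and 2.92 for siBLM and siBRCA1 in BRCA1del and 4.15 for siBRCA1 in BRCA1flox (blunt, lost). In the whole body the rightward calls were lost for siBRCA1 in BRCA1flox (3.73) and for genotype with siBLM (1.93), siBRCA1 (4.00) and siLuciferase (2.29). Uniquely placed reads lost siBLM in BRCA1del (3.87) and BRCA1flox (2.28) for the rightward share, and siBRCA1 in BRCA1del (4.74) and genotype with siBRCA1 (5.45) for blunt joins, with siBLM in BRCA1flox turned (0.162).

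Microhomology from 1 bp lost siFANCM in BRCA1del (-4.41) and genotype with siBLM (-4.72), siBRCA1 (-4.06) and siFANCM (-4.91), and turned siBLM (2.51), siBRCA1 (2.20) and siFANCM (1.25) in BRCA1flox and genotype with siLuciferase (0.738). From 4 bp it lost siFANCM in BRCA1del (-1.37) and genotype with siBLM (-4.82), siBRCA1 (-2.77), siFANCM (-2.58) and siLuciferase (-2.55), and turned siBLM in BRCA1flox (2.16). Leaving out each run in turn changed a call or direction in these differences. For the body they ranged from -5.44 to -3.24 (Tus against I-SceI), -8.92 to -0.544 (siFANCM in BRCA1del), -1.57 to 4.11 (siBLM in BRCA1del), and for genotype -6.83 to -0.804 (siFANCM), -8.55 to 0.372 (siBLM) and -8.23 to -3.52 (siBRCA1). For the rightward share they ranged from -4.49 to 4.48 (siFANCM in BRCA1del, which passed at -4.49 without run A and at 3.77 without run D), 2.62 to 8.11 (siBRCA1 in BRCA1del), and for genotype -3.21 to 5.87 (siFANCM) and 3.21 to 9.0 (siBRCA1). For microhomology they ranged from -10.3 to -5.00 (siFANCM in BRCA1del), -5.81 to 0.965 (siBLM in BRCA1del), -7.89 to -1.87 (siBRCA1 in BRCA1del), -20.8 to 1.47 (siFANCM in BRCA1flox), -9.23 to 0.756 (siBLM in BRCA1flox), -13.6 to -1.27 (siBRCA1 in BRCA1flox), and for genotype -16.6 to -7.54 (siBLM), -17.4 to -7.41 (siBRCA1) and -26.8 to -0.979 (siLuciferase). For blunt joins they ranged from 3.81 to 7.29 (siBLM in BRCA1del), 3.25 to 5.59 (siBRCA1 in BRCA1del), 2.43 to 5.99 (siBRCA1 in BRCA1flox) and 5.08 to 10.6 (genotype with siBRCA1).

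The genotype by siRNA interaction over runs, in percentage points instead of log odds, gave adjusted p = 0.0432 (rightward), 0.146 (body), 0.874 (blunt) and 0.874 (microhomology) by permutation of residuals, against 0.0016, 0.0805, 0.438 and 0.881. No paired analysis was possible by labelled replicate, because the tables carry no replicate numbers, and libraries were matched by sequencing run instead. Exact permutation over runs of 1 pair of groups cannot give p below 0.10, or 0.333 for 2 runs against 2, so it decides no pairwise call. Denominators without the bait window or from other chromosomes, windows of other widths, bait-proximal shares and recurrent prey regions were not run, since only cassette junctions were analysed here. Libraries of 148 junctions, and 11 rightward array joins in BRCA1flox siLuciferase, limit the precision.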

Other observations

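The test of the polyA-region reads below, and the counts of joins within Ter elements and left of the array, were chosen after the data were examined.

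Leftward Tus joins lay within the Ter elements more often than their length gives. The 6 elements cover 138 of the 234 bp of the pair of repeats, or 59.0%, and a read moved from 1 repeat to the other keeps its place inside or outside an element. In the 8 Tus groups 69.0% to 78.1% of leftward joins in the repeats lay within an element, with the lowest Wilson 95% bound at 65.0%. For rightward joins the share was 69.2% to 100%, from 10 to 120 joins per group, and the interval included 59.0% in 1 of 8 groups, BRCA1flox siBRCA1 (53.6% to 81.4%). With I-SceI, 106 leftward joins lay within an element, which was 39.7% of the 267 in the repeats but 91.4% of the 116 from the start of the first element to the end of the last, where the 8 Tus groups had 81.2% to 85.3%, so the order of I-SceI and Tus depends on the span.

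Rightward joins also occurred left of the array, within and before the EGFP start. They made up 18.3% to 28.1% of joins in that flank in the 4 BRCA1del Tus groups and 27.2% to 32.1% in the BRCA1flox groups. The difference of -5.06 points between the genotypes over runs did not pass (exact permutation p = 0.117), nor did the 8 run-matched pairs (exact sign-flip p = 0.289). Array joins lost a median of 8 to 11 bp of the bait end in the 4 BRCA1del Tus groups, 10 to 13 bp in the BRCA1flox groups and 10 bp with I-SceI, and no test was run on these losses.

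The polyA region held 4270 junctions over all groups and 463 of them came from EV. A candidate source is transfected plasmid carrying the same polyA sequences. Of 3701 placed polyA-region reads, 51.3% ran past the end of the matching segment into sequence that was neither cassette nor adapter, against 2.95% of 6824 body reads. Of the polyA-region reads, 1576 continued into 1 of 4 shared sequences, each seen in at least 20 reads, and 0 body reads did. Insertions of 10 bp or more stood at 31.4% of polyA-region joins and 4.07% of body joins. The region is the last part of the deposited positions, so rightward reads there can also run past the end of the reference. No plasmid sequence was given, so the origin of the shared sequences was not checked. The values go with a plasmid source but do not establish it, and no biological explanation was tested. The body shares, which have these junctions in their denominator, may depend on plasmid uptake as well as on joins at the cassette.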
